A study of Mus musculus with 12 samples.

How the data were processed

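RNA was taken from frozen testis with Trizol and made into libraries with a stranded polyA kit (TruSeq Stranded mRNA), per the labels' protocols. The deposited table held whole-number read counts per gene for all 12 libraries. The submitters' processing notes name Trimmomatic, STAR, featureCounts and DESeq2, and mm10 and GRCm38 as the genome build, and what each tool was used for is not given in the sources used here. Versions, the gene annotation and the settings for strand and for reads that map to several places are not given in the sources used here. The table held 21959 genes under Ensembl identifiers, of which 108 had no symbol and took 0.0504 to 0.0546% of the counts. Unassigned reads had no line in it. Gene positions and transcript lengths came from GENCODE release M21 on GRCm38.

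Libraries were grouped by their titles, because the descriptions give the third replicate of each treated group the number of the second. Total counts were 16570442, 18027090 and 17031754 in the saline libraries and 15533118, 16048177 and 19118265 at 50 mg/kg. They were 16680585, 18810691 and 16310555 at 100 mg/kg and 17274012, 14382378 and 17782695 at 200 mg/kg. The 10 most abundant genes took 3.936 to 4.66% of a library, and genes encoded by mitochondrial DNA 1.275 to 1.491%.

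Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, a robust quasi-likelihood fit of the 4 groups with 8 residual degrees of freedom, and contrasts of each dose with saline, of the mean of the 3 doses with saline, between doses and along dose as a number. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 15682 genes kept by the filter. The common biological coefficient of variation was 5.01% and the median prior degrees of freedom 16. The standard error of a log2 fold change was its size divided by the square root of its F value. On simulated counts for 50 mg/kg against saline over the same 15682 genes, with 50 changed genes at each size, the test recovered 28% of 1.2-fold, 76% of 1.5-fold, 86% of 2-fold and 94% of 4-fold changes, and 4.7% of its calls were false.

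Gene lists (39, covering inflammation, stress, metabolism, stages and structures of sperm, and other cells of the testis) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and with fry. A list needed 5 measured members. In a test on simulated data the 1 shifted list of 39 was called and 0 others.

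Genes were named by a rule. For each comparison with saline it took the 10 largest rises and the 10 largest falls among genes that passed, averaged at least 1 CPM, had no predicted-gene name and did not overlap between treated and control libraries. It added the 10 list members with the smallest p, the 2 to 4 members with the smallest p of each list described, and 28 genes of inflammation, oxidative stress, steroid synthesis and sperm function whatever their result. For the trend it took 5 genes in each direction by p, and for the test between doses, which has no direction, 10. Some genes that the rule took are not reported here, though they stay in the counts.

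Alternatives were RLE factors, library size alone, other count filters, DESeq2 1.42.0, limma voom with sample weights, a fit of the 2 groups compared, a fold limit with an unadjusted p, replicate number as a block, dose rank, an estimated correlation and leaving out each of the 12 libraries. Added after the data were seen were a fold limit of at least 2 on the calls, a fit without the 100 mg/kg libraries, and a length correction, in which a lowess trend (span 0.3) on transcript length was taken out of each library as an offset.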

Results

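Testis tissue from male mice of the ICR stock, an outbred laboratory stock, was profiled by sequencing polyadenylated RNA. The mice were 8 months old when dosing began and 9 months old at collection. They received saline or blueberry extract at 50, 100 or 200 mg/kg per day through a stomach tube, and each of the 4 groups had 3 libraries, 12 in all. The study asked, as its title states, whether the extract eases inflammation and the loss of sperm motility that comes with age. Library totals ran from 14382378 to 19118265 counts over 21959 genes, and 15682 genes had enough counts to be tested. All 12 libraries carried the same batch label. Separate animals are not stated for the 3 libraries of a group, so the p-values measure only the spread between these libraries, which may be technical.

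Libraries of a group lay close together, with a median within-group SD of 0.0665 (saline), 0.0728 (50 mg/kg), 0.112 (100 mg/kg) and 0.0671 (200 mg/kg) on the log2 scale, against 0.171 between the 4 group means. The first principal component held 39.4% of the variance and set the 100 mg/kg libraries apart from the other 9. Library 3 of the 100 mg/kg group stood apart from its own group, with a chi-square per degree of freedom of 12.42 against library 1 and 8.261 against library 2, while the other pairs within groups lay between 1.571 and 3.077.

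**Figure D1:**
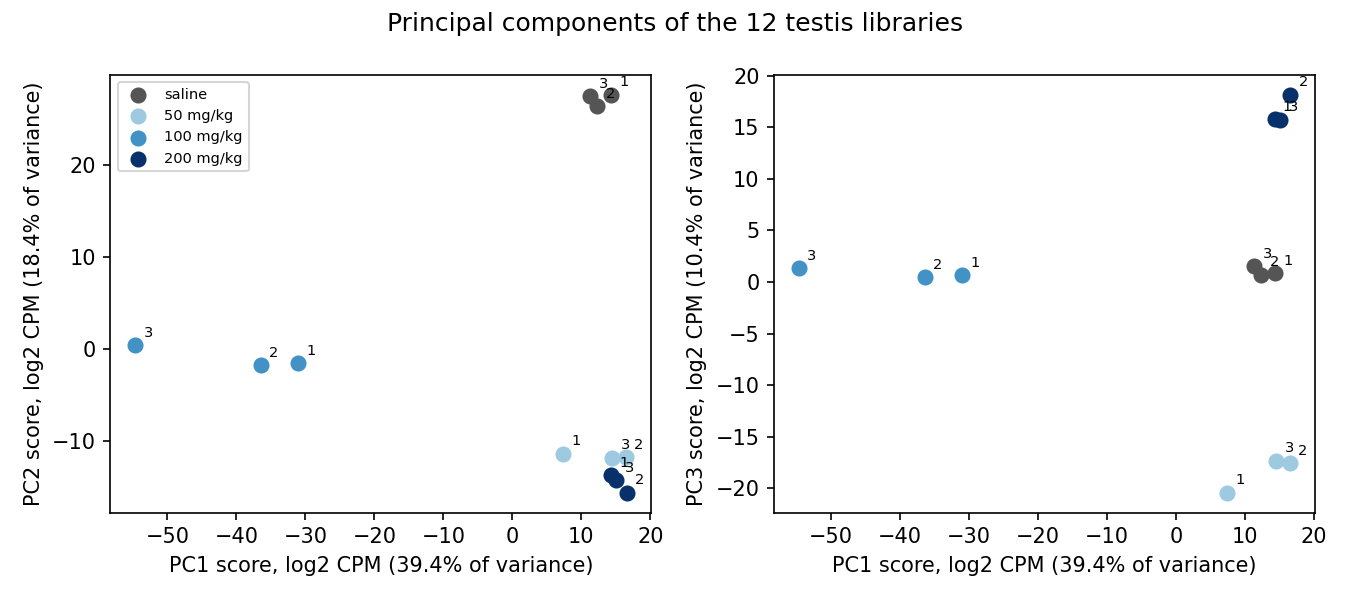
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, 1 point per library, numbered by replicate and coloured by dose. The 100 mg/kg libraries lie at scores of -54.7 to -31.01 on component 1, and the other libraries at 7.403 to 16.57.

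Some named genes share reads or positions with others, and their values are uncertain for that reason. These are the ribosomal protein, olfactory receptor, vomeronasal receptor, zinc finger and histocompatibility genes, which have close copies, and Atp5e, Uqcrh, C1rb, Cwc22, Dynlt1b, Aldh1a1 and Aldh1a7. Another 23 of the 163 named genes overlap a second gene of the table, and whether counting used strand is not given in the sources used here. Those 23 are Sirt2, Nfkbib, Eno4, Ogn, Rag1, Acss3, BC035947, Zc3h11a, Lancl3, Galntl6, Lpcat2, Tap1, Gss, Muc15, Pfkm, Tpi1, Cfap43, Tssk6, Myd88, mt-Nd5, mt-Atp6, Csf1r and Dnah17.

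The lowest dose was compared with saline to find what 50 mg/kg changed. Vgll2, a cofactor of TEAD transcription factors, was close to silent in saline testes and was read 211 times in the 50 mg/kg libraries against 1 count in the controls, a ratio of 211 with a 95% counting interval of 37.4 to 8350. The gene (ENSMUSG00000049641) lies on chromosome 10 from 52022502 to 52028471 of GRCm38. Ibsp, which encodes the bone matrix protein bone sialoprotein (ENSMUSG00000029306, chromosome 5 from 104299171 to 104311469), rose 23.7-fold, from 1.34 ± 0.39 to 31.8 ± 4.2 CPM (mean ± SD, n = 3). The calcium-handling genes of striated muscle Ryr1 and Casq1 rose 4.41-fold and 5.81-fold, and the growth factor gene Bmp3 rose 4.22-fold. Rps2, a protein of the small ribosomal subunit (ENSMUSG00000044533, chromosome 17 from 24718116 to 24721929), fell 7-fold, from 54.4 ± 1.7 to 7.78 ± 0.42 CPM. Other large falls were in Sftpb, a lung surfactant protein gene (12.4-fold), the cadherin gene Cdh22 (9.24-fold), the ATP-gated channel gene P2rx5 (7.1-fold) and the splicing factor gene Cwc22 (3.78-fold). Adjusted p-values of these genes ran from 3.87e-17 to 1.25e-05. Intervals on counts cover counting error only. The other named rises were in Pcdh9, Olfr873, Zfp820, Zfp937 and Vmn1r224 (4.14-fold to 8.34-fold), and the other named falls in Lhfpl3, Zfp951, Cyp2b10, C1rb and Svs5 (3.89-fold to 11.5-fold).

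Sirt2, a deacetylase gene (0.88 ± 0.055), Catspere2 of the CatSper channel (0.86 ± 0.069), Nlrc5, the activator of class I histocompatibility genes (1.82 ± 0.15), the meiotic endonuclease gene Spo11 (0.73 ± 0.065) and the IgG receptor gene Fcgr3 (1.04 ± 0.095) rose on the log2 scale (± SE), and the matrix gene Ogn fell (-0.76 ± 0.076). Of the 39 gene lists, fixed before the data were examined like the tests and the rule for naming genes, 5 passed camera's test at 50 mg/kg, all downward. Of 25 markers of Sertoli cells, the nurse cells of the seminiferous tubule, 1 rose and 10 fell (1 and 12 adjusted over the list alone). The Sertoli cell list had a median log2 fold change of -0.22 (camera adjusted p = 0.0043, adjusted p = 0.47 with an estimated correlation). Clu changed by -0.33 ± 0.043 and Ctsl by -0.23 ± 0.038 on the log2 scale, while the cystatin gene Cst9 of the same list rose 2.47-fold (1.30 ± 0.062). Among 23 genes of cholesterol synthesis, 1 rose and 7 fell (1 and 8 adjusted over the list alone). The cholesterol synthesis list had a median log2 fold change of -0.17 (camera adjusted p = 0.0043, adjusted p = 0.108 with an estimated correlation), and Sqle (squalene epoxidase) changed by -0.22 ± 0.049, Insig1 by -0.36 ± 0.093 and Msmo1 by -0.26 ± 0.066. For 20 genes of germ-cell glycolysis, 2 rose and 9 fell (2 and 12 adjusted over the list alone). The glycolysis list had a median log2 fold change of -0.13 (camera adjusted p = 0.0207, adjusted p = 0.387 with an estimated correlation), with Pfkm at -0.25 ± 0.045 and Tpi1 at -0.23 ± 0.044, while Eno4, a sperm enolase, rose (0.64 ± 0.057). In the list of 70 nuclear genes of oxidative phosphorylation, 1 rose and 10 fell (1 and 10 adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of -0.088 (camera adjusted p = 0.0263, adjusted p = 0.879 with an estimated correlation), with Sdhc at -0.30 ± 0.066, Uqcrc1 at -0.26 ± 0.057 and Atp5e up at 0.83 ± 0.12. Of 76 ribosomal protein genes, 2 rose and 10 fell (1 and 9 adjusted over the list alone). The ribosomal list had a median log2 fold change of -0.061 (camera adjusted p = 0.0236, adjusted p = 0.902 with an estimated correlation), with Rpl26 at -0.66 ± 0.061 and Rpl35a at -0.60 ± 0.072. Msmo1 lost its call at adjusted p = 0.0713 without 50 mg/kg library 3, within 0.00103 to 0.0713 over all its alternatives. Leaving out 50 mg/kg library 2 left 3 lists called, and leaving out 100 mg/kg library 3 gave 8. The oxidative phosphorylation call was lost at adjusted p = 0.0914 without 50 mg/kg library 2 and 0.0841 without 50 mg/kg library 3, 0.389 in fry, within 0.00332 to 0.879 over all its alternatives. The ribosomal call was lost at adjusted p = 0.0648 without 50 mg/kg library 2 and 0.057 without 50 mg/kg library 3, 0.215 in fry, within 0.00332 to 0.902 over all its alternatives. No list passed with an estimated correlation (preset 0.01) in any comparison with saline. Fry tests whether list members move, on balance, 1 way and does not compare them with other genes.

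Of 25 measured genes of NF-kB signalling, 1 rose and 1 fell (1 and 1 adjusted over the list alone). The NF-kB list had a median log2 fold change of -0.0058 (camera adjusted p = 0.987, adjusted p = 0.987 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, rose (0.32 ± 0.046, adjusted p = 3.35e-05) and the TNF receptor gene Tnfrsf1b fell (-0.78 ± 0.21, adjusted p = 0.0135). Il1b (0.18 ± 0.29, adjusted p = 0.732), Nfkb1 (-0.0058 ± 0.089, adjusted p = 0.976), Rela (-0.20 ± 0.070, adjusted p = 0.0525) and Tlr4 (0.38 ± 0.34, adjusted p = 0.485) did not pass. Tnf, Il6, Nlrp3 and Ccl2 had 6, 0, 25 and 24 counts in all 12 libraries together and were not tested. Among antioxidant genes, log2 fold changes were -0.13 ± 0.14 for Hmox1, 0.24 ± 0.18 for Nqo1, -0.065 ± 0.058 for Sod2, -0.10 ± 0.067 for Gpx4 and -0.23 ± 0.11 for Cat, none past the threshold (adjusted p from 0.162 to 0.58). Sirt1 (0.10 ± 0.067, adjusted p = 0.308), Cdkn1a (-0.019 ± 0.13, adjusted p = 0.944) and the macrophage gene Adgre1 (0.040 ± 0.17, adjusted p = 0.909) did not pass either. In the steroid pathway Star, which moves cholesterol into mitochondria, rose (0.32 ± 0.048, adjusted p = 4.86e-05). Cyp11a1 (-0.53 ± 0.056, adjusted p = 2.62e-07) and Cyp17a1 (-0.18 ± 0.042, adjusted p = 0.00414) fell, and Hsd17b3 did not pass (0.070 ± 0.058, adjusted p = 0.45). Akap4 of the fibrous sheath of sperm (-0.12 ± 0.036, adjusted p = 0.0282), the flagellar dynein gene Dnah1 (-0.16 ± 0.046, adjusted p = 0.019) and the Sertoli cell tight junction gene Cldn11 (-0.20 ± 0.055, adjusted p = 0.013) fell. Values for Prm1 (-0.025 ± 0.084), Tnp1 (0.40 ± 0.16), Catsper1 (-0.048 ± 0.046), Gapdhs (-0.13 ± 0.053) and Ldhc (0.023 ± 0.036) did not pass (adjusted p from 0.106 to 0.879). Akap4 lost its call at adjusted p = 0.0534 to 0.105 without control library 1, 2 or 3 or 50 mg/kg library 1, 2 or 3, 0.13 on library size alone, within 5.07e-06 to 0.13 over all its alternatives. Dnah1 lost its call at adjusted p = 0.0524 to 0.107 without control library 2 or 3 or 50 mg/kg library 1 or 3, 0.0613 on library size alone, within 0.000804 to 0.107 over all its alternatives. Cldn11 lost its call at adjusted p = 0.0752 without control library 3 and 0.0609 without 50 mg/kg library 3, within 0.00148 to 0.0752 over all its alternatives. Tnfrsf1b lost its call at adjusted p = 0.113 without control library 2 and 0.0548 without 50 mg/kg library 3, within 0.00354 to 0.113 over all its alternatives. Rela gained a call at adjusted p = 0.0181 to 0.0431 without control library 1 or 50 mg/kg library 1 or 100 mg/kg library 1 or 3, 0.0369 without the count filter, 0.00633 in limma voom, 0.0322 after the length correction, 0.02 without the 100 mg/kg libraries, 0.0241 in the fit of those groups alone, within 0.00633 to 0.255 over all its alternatives. Gpx4 gained a call at adjusted p = 0.016 without 100 mg/kg library 3, 0.0178 without the 100 mg/kg libraries, 0.00826 in the fit of those groups alone, within 0.00826 to 0.577 over all its alternatives. Gapdhs gained a call at adjusted p = 0.00122 without 100 mg/kg library 3, 0.00465 in limma voom, 0.0496 after the length correction, 0.00133 without the 100 mg/kg libraries, 0.000689 in the fit of those groups alone, within 0.000689 to 0.239 over all its alternatives. Tnp1 gained a call at adjusted p = 0.0235 without control library 2, within 0.0232 to 0.252 over all its alternatives.

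Of the 15682 genes tested, 2701 differed between 50 mg/kg and saline in edgeR's quasi-likelihood test, 1444 higher and 1257 lower, and 309 of them by at least 2-fold (230 higher, 79 lower). The treated and control libraries did not overlap in 2657 of the called genes and in 37.6% of all genes, where chance gives 10%. The 3 treated libraries lay beyond the 3 controls in all 48 named genes that passed, which the naming rule required of 20 of them. The count was 1738 without control library 2, 1714 without control library 3 and 1714 without 50 mg/kg library 3, and limma voom called 4145. Scaling by library size alone gave 1759 higher and 878 lower.

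**Figure D2:**
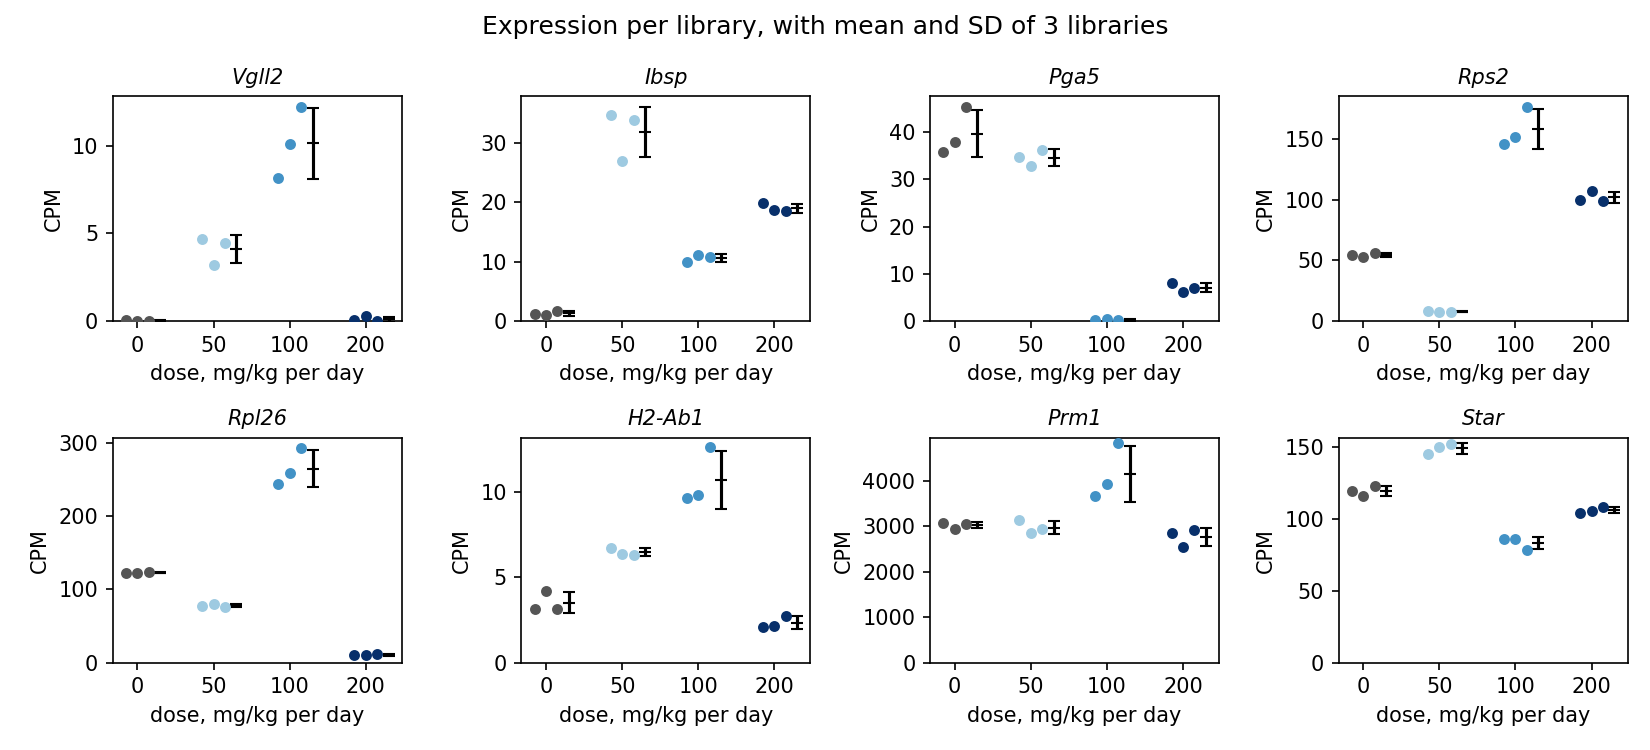
Expression of 8 genes in CPM (vertical axes, from 0) by dose in mg/kg per day, 1 point per library, with the mean and SD of 3 libraries beside them. Vgll2 averages 10.1 CPM at 100 mg/kg and 0.0204 CPM in controls, and Rpl26 averages 10.8 CPM at 200 mg/kg and 123 CPM in controls.

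The middle dose was compared with saline in the same way. Vgll2 had 525 counts at 100 mg/kg against 1 in the controls, a ratio of 515 with a counting interval of 92 to 20400. At 200 mg/kg it had 5 counts, close to silent again. Cxcl13, a chemokine that attracts B cells, went up 26.9-fold, from 0.319 ± 0.16 to 8.68 ± 1.4 CPM, Jchain, which joins secreted antibodies, 9.49-fold, the recombinase gene Rag1 9.96-fold and Cd8b1 4.86-fold, while Crtam, a lymphocyte adhesion gene, fell 6.5-fold. The list of 6 lymphocyte markers (median length 1623 bases) did not pass, with a median log2 fold change of 0.59 (camera adjusted p = 0.117, adjusted p = 0.423 with an estimated correlation). Pga5, a pepsinogen gene (ENSMUSG00000024738, chromosome 19 from 10668956 to 10678071), fell 119-fold, from 39.7 ± 4.9 to 0.318 ± 0.18 CPM, and the copper transporter gene Atp7a fell 7.2-fold. Among 36 meiosis genes (median length 1687 bases) 8 rose and 13 fell (8 and 13 adjusted over the list alone), and the list did not pass, with a median log2 fold change of 0.049 and a mean of -0.21 (camera adjusted p = 0.508, adjusted p = 0.532 with an estimated correlation). Its members Sycp1 and Sycp2 of the synaptonemal complex fell 2.94-fold and 3-fold, the meiotic cohesin gene Smc1b 2.2-fold and Tex15 1.95-fold. The other named rises were in Casq1, Pcdh9, Ibsp, Zfp981 and Vmn1r224 (5.29-fold to 8.78-fold), and the other named falls in Aff2, Acss3, BC035947, Zc3h11a, Pm20d2, Lancl3 and Adcy9 (5.26-fold to 8.36-fold). Cylc1 and Cylc2 of the sperm head cytoskeleton (-1.02 ± 0.053 and -1.12 ± 0.046), the CatSper-associated gene C2cd6 (-0.96 ± 0.049) and the matrix gene Ogn (-1.30 ± 0.080) also fell.

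At 100 mg/kg the fold changes followed transcript length. Across 14404 genes the rank correlation of fold change with length was -0.415 (0.0173 at 50 mg/kg, 0.108 at 200 mg/kg), where genes are not independent replicates. The median log2 fold change was 0.33 for the 228 genes under 500 bases and -0.39 for the 810 genes of at least 6000 bases. The lists set against saline at this dose are given with the median transcript length of their members.

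**Figure D3:**
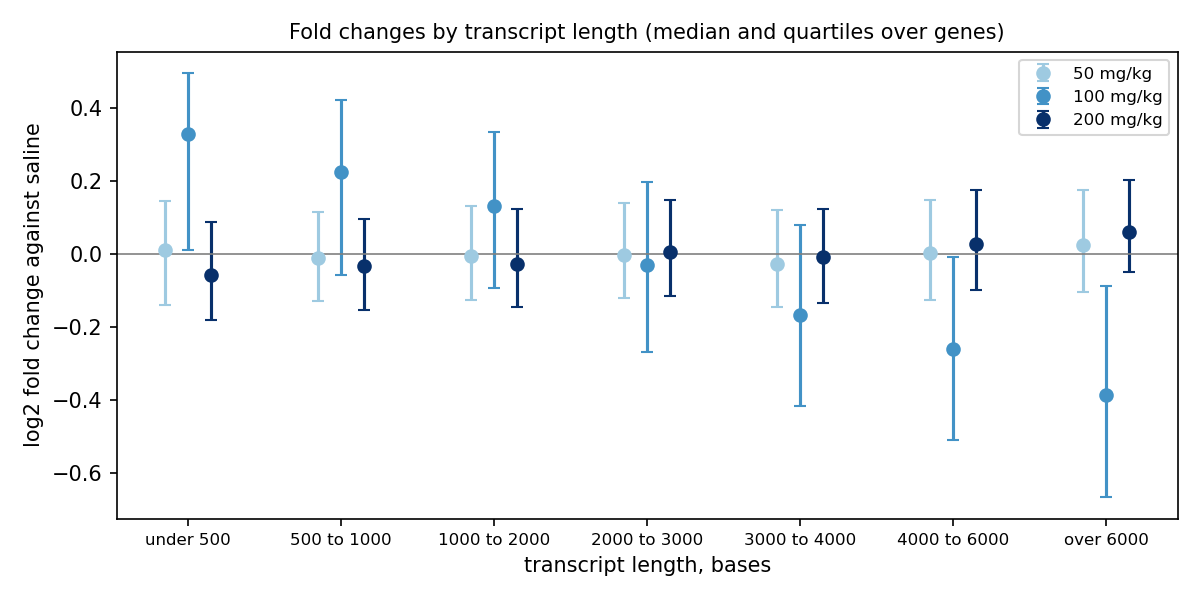
Median log2 fold change against saline (vertical axis, with quartiles over genes) by class of transcript length in bases (horizontal axis), 1 point per class and dose. At 100 mg/kg the median goes from 0.33 in the shortest class to -0.39 in the longest, and at 50 mg/kg it lies between -0.026 and 0.026.

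At 100 mg/kg 8 lists passed camera's test. Of 76 ribosomal protein genes (median length 719 bases), 62 rose and 0 fell (64 and 0 adjusted over the list alone). The ribosomal list had a median log2 fold change of 0.40 (camera adjusted p = 1.52e-12, adjusted p = 0.465 with an estimated correlation). Rps2 rose 2.9-fold, Rpl26 2.15-fold and Rpl21 4.66-fold. Among 70 nuclear genes of oxidative phosphorylation (653 bases), 48 rose and 3 fell (50 and 3 adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of 0.36 (camera adjusted p = 8.44e-08, adjusted p = 0.532 with an estimated correlation), with the sperm subunit gene Cox6b2 at 0.74 ± 0.064, Atp5e at 1.54 ± 0.12 and Uqcrh at 0.49 ± 0.054. For 15 genes of antigen presentation (977 bases), 11 rose and 1 fell (12 and 1 adjusted over the list alone). The antigen presentation list had a median log2 fold change of 0.79 (camera adjusted p = 0.0081, adjusted p = 0.423 with an estimated correlation). The class II gene H2-Ab1 rose 3.03-fold, from 3.5 ± 0.62 to 10.7 ± 1.7 CPM, H2-Eb1 3.36-fold and the peptide transporter gene Tap1 2.81-fold. Of 21 immediate early genes (2108 bases), 9 rose and 1 fell (8 and 1 adjusted over the list alone). The immediate early list had a median log2 fold change of 0.33 (camera adjusted p = 0.0492, adjusted p = 0.423 with an estimated correlation), with Egr3 at 1.33 ± 0.13, Egr1 at 1.11 ± 0.14 and Klf6 down at -0.63 ± 0.12. In the blood-testis barrier list of 20 genes (2130 bases), 3 rose and 12 fell (3 and 12 adjusted over the list alone). The barrier list had a median log2 fold change of -0.32 (camera adjusted p = 0.0327, adjusted p = 0.423 with an estimated correlation), and Tjp1 (-0.82 ± 0.071), Itgb1 (-0.59 ± 0.066) and F11r (-0.79 ± 0.087) were among those that fell. The immediate early call was lost at adjusted p = 0.0551 to 0.111 without control library 1 or 2 or 100 mg/kg library 1, 0.0523 with RLE factors, within 0.000136 to 0.423 over all its alternatives. After the length correction, which was added after the data were seen, the median was 0.20 for the ribosomal list and 0.17 for the oxidative phosphorylation list, and Uqcrh stood on the log2 scale at 0.27, Tjp1 at -0.49 and Klf6 at -0.40. Without 100 mg/kg library 3 the antigen presentation median was 0.51.

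The other 3 of the 8 lists were of sperm structures, and none of the 3 passed after the length correction, which took their medians to -0.062 (axoneme), 0.18 (protamine) and 0.10 (acrosome). Among 59 genes of the axoneme and flagellum (2623 bases), 13 rose and 31 fell (15 and 31 adjusted over the list alone). The axoneme list had a median log2 fold change of -0.18 (camera adjusted p = 0.0273, adjusted p = 0.423 with an estimated correlation). Cfap43 (-0.79 ± 0.058) and Hydin (-0.69 ± 0.056) fell and Rsph1 rose (0.50 ± 0.038), and the call was lost at adjusted p = 0.139 after the length correction, within 8.63e-05 to 0.423 over all its alternatives. Of 13 genes of the histone to protamine transition (746 bases), 10 rose and 2 fell (10 and 2 adjusted over the list alone). The protamine list had a median log2 fold change of 0.29 (camera adjusted p = 0.0327, adjusted p = 0.443 with an estimated correlation). The protamine call was lost at adjusted p = 0.064 after the length correction, within 0.00115 to 0.443 over all its alternatives. Its members Chd5 (-0.40 ± 0.056) and Brdt (-0.28 ± 0.043) fell and Tssk6 rose (0.49 ± 0.083). For 28 genes of the acrosome and fertilization (1125 bases), 17 rose and 5 fell (18 and 5 adjusted over the list alone). The acrosome list had a median log2 fold change of 0.25 (camera adjusted p = 0.014, adjusted p = 0.423 with an estimated correlation). The acrosome call was lost at adjusted p = 0.081 after the length correction, within 0.000134 to 0.423 over all its alternatives. Tmem95 (0.87 ± 0.072) and Fam209 (0.63 ± 0.060) rose and Pkdrej fell (-0.72 ± 0.057). After the correction Chd5 was at 0.032, adjusted p = 0.507 (7.76e-12 to 0.507 over its alternatives), so that its call ended and its sign turned. The correction left Hydin at -0.12, Brdt at -0.14 and Pkdrej at -0.35.

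Of 25 NF-kB genes at 100 mg/kg (median length 2396 bases), 3 rose and 8 fell (3 and 7 adjusted over the list alone). The NF-kB list had a median log2 fold change of -0.16 (camera adjusted p = 0.498, adjusted p = 0.532 with an estimated correlation). Nfkbib, an inhibitor of NF-kB, rose (0.49 ± 0.058, adjusted p = 1.78e-07), Rela rose (0.20 ± 0.068, adjusted p = 0.017), and Vcam1 (-0.37 ± 0.047, adjusted p = 5.51e-07), the interleukin receptor gene Il1r1 (-0.56 ± 0.10, adjusted p = 6.66e-05) and Tlr4 (-1.19 ± 0.42, adjusted p = 0.0196) fell. Il1b (-0.14 ± 0.30, adjusted p = 0.725) and Nfkb1 (-0.067 ± 0.090, adjusted p = 0.557) did not pass. Sod2 (0.16 ± 0.058) and Gpx4 (0.46 ± 0.067) rose and Cat fell (-0.67 ± 0.11), with adjusted p = 0.0224, 1.5e-05 and 2.45e-05. Hmox1 (0.0077 ± 0.14, adjusted p = 0.969) and Nqo1 (0.0055 ± 0.18, adjusted p = 0.983) did not pass. Sirt1 fell (-0.35 ± 0.069, adjusted p = 0.000145), as did Star (-0.52 ± 0.050, adjusted p = 1.09e-08), Cyp11a1 (-0.53 ± 0.056, adjusted p = 3.57e-08) and Hsd17b3 (-0.18 ± 0.059, adjusted p = 0.0115). Cyp17a1 (-0.058 ± 0.042, adjusted p = 0.252), Cldn11 (-0.042 ± 0.054, adjusted p = 0.543), Cdkn1a (0.25 ± 0.12, adjusted p = 0.0972), Adgre1 (0.30 ± 0.17, adjusted p = 0.136) and Catsper1 (0.021 ± 0.046, adjusted p = 0.724) did not pass. The protamine gene Prm1 (0.46 ± 0.084), the transition protein gene Tnp1 (1.04 ± 0.15), Gapdhs (0.39 ± 0.053) and Ldhc (0.31 ± 0.036) rose, with adjusted p from 1.45e-07 to 0.000532. Akap4 (-0.32 ± 0.036, adjusted p = 1.31e-07) and Dnah1 (-0.36 ± 0.046, adjusted p = 6.22e-07) fell, and Dnah1 turned to 0.16, adjusted p = 0.00413 after the length correction (7.67e-12 to 0.00413 over its alternatives). After that correction Prm1 stood on the log2 scale at 0.22, Ldhc at 0.13, Il1r1 at -0.27 and Gpx4 at 0.27, nearer to 0, and Hsd17b3 at -0.35 and Sod2 at 0.30, further from it. It put Rela at 0.11 and Sirt1 at -0.15. Sod2 was at 0.090 without 100 mg/kg library 3 and at 0.088 in limma voom. Rela lost its call at adjusted p = 0.0916 without control library 1, 0.168 after the length correction, within 0.00789 to 0.168 over all its alternatives. Tlr4 lost its call at adjusted p = 0.0556 without control library 1 and 0.108 without 100 mg/kg library 2, 0.0571 in DESeq2, within 0.000571 to 0.108 over all its alternatives. Sod2 lost its call at adjusted p = 0.147 without control library 2 and 0.112 without 100 mg/kg library 3, 0.0809 in limma voom, 0.069 in the fit of those groups alone, within 0.000208 to 0.147 over all its alternatives. Sirt1 lost its call at adjusted p = 0.0577 after the length correction, within 3.99e-07 to 0.0577 over all its alternatives. Cyp17a1 gained a call at adjusted p = 0.0206 without 100 mg/kg library 3, 0.0355 in limma voom, within 0.0206 to 0.584 over all its alternatives. Cdkn1a gained a call at adjusted p = 0.0315 without control library 3, within 0.0315 to 0.572 over all its alternatives. Adgre1 gained a call at adjusted p = 0.023 in limma voom, within 0.023 to 0.586 over all its alternatives.

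In all, 8212 of 15682 genes differed between 100 mg/kg and saline, 4010 higher and 4202 lower, and 679 of them by at least 2-fold (325 higher, 354 lower). The libraries did not overlap in 7857 of the called genes and in 58.7% of all genes (chance 10%), and the 3 treated libraries lay beyond the controls in all 70 named genes that passed, as required of 20 of them by the rule. After the length correction 7403 genes were called, 6066 of them among the 8212, whatever their direction.

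The highest dose was compared with saline next. Rpl26, a protein of the large ribosomal subunit (ENSMUSG00000060938, chromosome 11 from 68901583 to 68906989), fell 11.3-fold, from 123 ± 0.76 to 10.8 ± 1.2 CPM, and Cdh22 fell 15.6-fold. Galntl6, a gene of the family that starts O-glycosylation, fell 8.76-fold, Pga5 5.54-fold, the macrophage glycoprotein gene Gpnmb 4.31-fold and Aldh1a7 3.24-fold. The zinc finger genes Zfp981 (ENSMUSG00000056300, chromosome 4 from 146502027 to 146539395) and Zfp991 rose 18.6-fold and 8.05-fold. Ibsp rose 14.2-fold to 19 ± 0.75 CPM, Bmp3 5.74-fold and Cd8b1 5.17-fold. The other named rises were in Olfr873, Casq1, Pcdh9, Vmn1r224 and Olfr16 (5.49-fold to 6.41-fold), and the other named falls in Zfp951, C1rb, Lpcat2 and Tap1 (3.32-fold to 7.11-fold). Among list members, the meiotic endonuclease gene Spo11 (0.96 ± 0.064), Catspere2 of the CatSper channel (0.97 ± 0.069), Cst8 (0.54 ± 0.051) and Rps2 (0.91 ± 0.064) rose and Sycp1 fell (-0.69 ± 0.054).

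At 200 mg/kg 11 lists passed camera's test, 10 of them downward. The lymphocyte list did not pass and had a median log2 fold change of 0.51 (camera adjusted p = 0.0503, adjusted p = 0.24 with an estimated correlation). Of 13 complement genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone). The complement list had a median log2 fold change of -0.46 (camera adjusted p = 0.000587, adjusted p = 0.0906 with an estimated correlation), with C4b at -0.59 ± 0.075, Serping1 at -0.53 ± 0.082 and C3 at -0.86 ± 0.14. Among 15 genes of antigen presentation, 1 rose and 8 fell (1 and 8 adjusted over the list alone). The antigen presentation list had a median log2 fold change of -0.48 (camera adjusted p = 0.000606, adjusted p = 0.24 with an estimated correlation). Tap1 (-1.73 ± 0.22) and the class I gene H2-D1 (-0.47 ± 0.084) fell while Nlrc5, the activator of class I genes, rose (1.11 ± 0.17). For 18 macrophage markers, 2 rose and 6 fell (2 and 10 adjusted over the list alone). The macrophage list had a median log2 fold change of -0.32 (camera adjusted p = 0.019, adjusted p = 0.16 with an estimated correlation), with Lyz2 at -0.60 ± 0.081, Csf1r at -0.63 ± 0.13 and Fcgr3 up at 0.55 ± 0.099. Of 24 fibroblast and matrix genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone). The fibroblast list had a median log2 fold change of -0.15 (camera adjusted p = 0.0319, adjusted p = 0.24 with an estimated correlation), with Ogn at -0.55 ± 0.076, Sparc at -0.29 ± 0.042 and Dcn at -0.37 ± 0.056. In the Sertoli cell list of 25 genes, 1 rose and 11 fell (1 and 14 adjusted over the list alone). The Sertoli cell list had a median log2 fold change of -0.29 (camera adjusted p = 6.2e-06, adjusted p = 0.16 with an estimated correlation), with Clu at -0.49 ± 0.043 and Ctsl at -0.40 ± 0.038 but Cst9 up 2.3-fold. The macrophage call was lost at adjusted p = 0.0722 without 200 mg/kg library 2, within 0.00124 to 0.16 over all its alternatives. The fibroblast call was lost at adjusted p = 0.0536 without control library 2 and 0.0904 without 200 mg/kg library 3, within 0.00341 to 0.24 over all its alternatives.

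Mitochondrial, antioxidant, cholesterol and ribosomal lists were also among those that fell. Of 12 genes encoded by mitochondrial DNA, 0 rose and 8 fell (0 and 9 adjusted over the list alone). The mitochondrially encoded list had a median log2 fold change of -0.27 (camera adjusted p = 0.000284, adjusted p = 0.307 with an estimated correlation), with mt-Nd5 at -0.51 ± 0.050, mt-Nd1 at -0.33 ± 0.063 and mt-Atp6 at -0.44 ± 0.11. Among 70 nuclear genes of oxidative phosphorylation, 1 rose and 15 fell (1 and 16 adjusted over the list alone). The oxidative phosphorylation list had a median log2 fold change of -0.12 (camera adjusted p = 0.000188, adjusted p = 0.598 with an estimated correlation), with Cox7b2 at -0.34 ± 0.052, Cycs at -0.34 ± 0.066 and Atp5e up at 0.69 ± 0.12. For 33 antioxidant genes, 2 rose and 11 fell (2 and 15 adjusted over the list alone). The antioxidant list had a median log2 fold change of -0.15 (camera adjusted p = 0.000547, adjusted p = 0.315 with an estimated correlation), with the glutathione synthetase gene Gss at -1.14 ± 0.10, Srxn1 at -0.48 ± 0.069 and Gstm1 at -0.31 ± 0.052. In cholesterol synthesis, with 23 genes, 0 rose and 8 fell (1 and 10 adjusted over the list alone). The cholesterol synthesis list had a median log2 fold change of -0.13 (camera adjusted p = 0.00213, adjusted p = 0.0906 with an estimated correlation), with Msmo1 at -0.28 ± 0.067, Sc5d at -0.30 ± 0.088 and Ebp at -0.45 ± 0.11. Of 76 ribosomal protein genes, 2 rose and 22 fell (2 and 27 adjusted over the list alone). The ribosomal list had a median log2 fold change of -0.14 (camera adjusted p = 6.2e-06, adjusted p = 0.598 with an estimated correlation), with Rpl26 at -3.50 ± 0.078, Rpl35a at -0.99 ± 0.075 and Rps2 up at 0.91 ± 0.064. Without 200 mg/kg library 2 mt-Atp6 was at -0.28. Fry did not call the oxidative phosphorylation list (adjusted p = 0.144 in fry, within 1.21e-05 to 0.598 over all its alternatives). The circadian clock was the list that rose, and of its 19 genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone). The circadian clock list had a median log2 fold change of 0.20 (camera adjusted p = 0.0319, adjusted p = 0.24 with an estimated correlation), with Per1 at 0.33 ± 0.051, Rora at 0.33 ± 0.063 and Tef at 0.28 ± 0.068. The clock call was lost at adjusted p = 0.126 without control library 2 and 0.052 without 200 mg/kg library 3, 0.0619 after the length correction, within 0.00239 to 0.24 over all its alternatives. Ebp lost its call at adjusted p = 0.0559 without control library 3, within 0.000173 to 0.0559 over all its alternatives. Sc5d lost it at adjusted p = 0.0549 to 0.0722 without control library 2 or 200 mg/kg library 1 or 2, within 0.00573 to 0.0722 over all its alternatives.

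**Figure D4:**
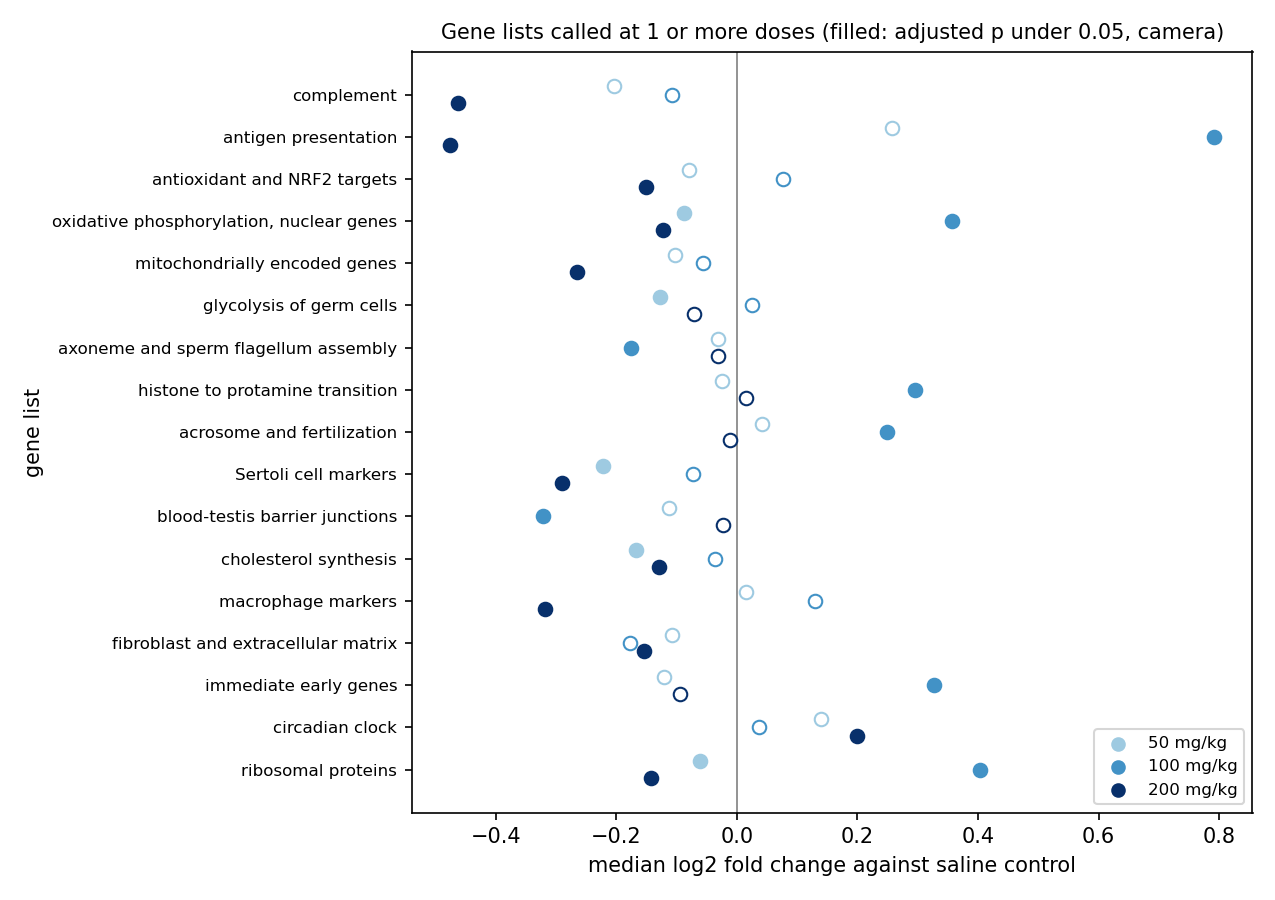
Median log2 fold change against saline (horizontal axis) of the 17 gene lists that passed camera's test at 1 or more doses, 1 point per dose, filled where the list passed at that dose. Antigen presentation stands at 0.79 at 100 mg/kg and -0.48 at 200 mg/kg, and no filled point held with an estimated correlation.

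Of 25 NF-kB genes at 200 mg/kg, 3 rose and 3 fell (3 and 3 adjusted over the list alone). The NF-kB list had a median log2 fold change of 0.016 (camera adjusted p = 0.862, adjusted p = 0.878 with an estimated correlation). Their mean log2 fold change was -0.017, so median and test differed in sign. Vcam1 (0.27 ± 0.046, adjusted p = 0.000192) and Myd88, an adaptor of Toll-like receptors, (0.38 ± 0.096, adjusted p = 0.00699) rose, and Tnfrsf1a (-0.46 ± 0.099, adjusted p = 0.00181) and Nfkb1 (-0.29 ± 0.092, adjusted p = 0.0291) fell. Il1b (0.68 ± 0.28, adjusted p = 0.0894), Rela (-0.12 ± 0.070, adjusted p = 0.265) and Tlr4 (-0.73 ± 0.40, adjusted p = 0.217) did not pass. Heme oxygenase gene Hmox1 fell (-0.60 ± 0.15, adjusted p = 0.00568), while Nqo1 (-0.21 ± 0.19), Sod2 (-0.091 ± 0.058), Gpx4 (-0.093 ± 0.067), Cat (-0.083 ± 0.11) and Sirt1 (0.090 ± 0.067) did not pass (adjusted p from 0.307 to 0.648). Star (-0.17 ± 0.049, adjusted p = 0.0161), Cyp11a1 (-0.30 ± 0.055, adjusted p = 0.000366), Cyp17a1 (-0.13 ± 0.042, adjusted p = 0.0305), Gapdhs (-0.18 ± 0.053, adjusted p = 0.0234) and Cldn11 (-0.30 ± 0.055, adjusted p = 0.000379) fell. Hsd17b3 (0.097 ± 0.058), Prm1 (-0.13 ± 0.084), Tnp1 (0.23 ± 0.16), Akap4 (-0.065 ± 0.036), Catsper1 (-0.031 ± 0.046), Dnah1 (-0.0089 ± 0.046), Ldhc (0.033 ± 0.036), Cdkn1a (-0.046 ± 0.13) and Adgre1 (-0.094 ± 0.18) did not pass (adjusted p from 0.228 to 0.92). Myd88 lost its call at adjusted p = 0.0559 without control library 3 and 0.065 without 200 mg/kg library 3, within 0.000982 to 0.065 over all its alternatives. Nfkb1 lost its call at adjusted p = 0.0533 to 0.14 without control library 2 or 3 or 200 mg/kg library 1 or 2, 0.0574 in DESeq2, within 0.0136 to 0.14 over all its alternatives. Hmox1 lost its call at adjusted p = 0.0586 without control library 3, within 3e-04 to 0.0586 over all its alternatives. Star lost its call at adjusted p = 0.0818 without control library 3 and 0.0767 without 200 mg/kg library 1, within 0.00026 to 0.0818 over all its alternatives. Cyp17a1 lost its call at adjusted p = 0.0509 to 0.137 without control library 1 or 2 or 200 mg/kg library 1, 2 or 3, 0.0596 on library size alone, within 5.3e-05 to 0.137 over all its alternatives. Gapdhs lost its call at adjusted p = 0.0627 to 0.149 without control library 2 or 3 or 200 mg/kg library 2, within 4.74e-06 to 0.149 over all its alternatives. Il1b gained a call at adjusted p = 0.0494 in limma voom, within 0.0494 to 0.359 over all its alternatives. Gpx4 gained a call at adjusted p = 0.0206 without 100 mg/kg library 3, 0.0183 without the 100 mg/kg libraries, within 0.0183 to 0.64 over all its alternatives. Akap4 gained a call at adjusted p = 0.0269 without 100 mg/kg library 3, 0.00779 in limma voom, 0.016 without the 100 mg/kg libraries, 0.0168 in the fit of those groups alone, within 0.00779 to 0.468 over all its alternatives. Dnah1 gained a call at adjusted p = 0.0401 after the length correction, within 0.0401 to 0.972 over all its alternatives.

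At 200 mg/kg 2914 genes differed from saline, 1612 higher and 1302 lower, and 350 of them by at least 2-fold (279 higher, 71 lower). The libraries did not overlap in 2841 of the called genes and in 39.2% of all genes (chance 10%). In 64 of the 65 named genes that passed, 20 of them chosen for it, the 3 treated libraries lay beyond the controls, and for Hmox1 2 of 3 did. The count was 1941 without 200 mg/kg library 1, and a fit of the saline and 200 mg/kg groups alone called 4439.

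The mean of the 3 doses was set against saline to test the average of the treated groups, which need not share a direction. Ibsp (13.9-fold), Pcdh9 (7.53-fold), Casq1 (6.82-fold), Cavin4 (3.85-fold), Crip3 (3.69-fold) and Cd8b1 (3.98-fold) rose. Cdh22 (6.63-fold), Gpnmb (3.45-fold), Crtam (3.34-fold), Fnbp1l (2.55-fold, from 148 ± 1.7 CPM in saline) and the water channel gene Aqp2 (2.49-fold) fell. Vmn1r224, Olfr873, Olfr16 and Zfp820 also rose (3.78-fold to 4.97-fold), and Zfp951, Lhfpl3, C1rb, Svs5 and Pm20d2 fell (2.5-fold to 5.63-fold). Sirt2 (0.63 ± 0.047), Spo11 (0.74 ± 0.055), Catspere2 (0.83 ± 0.058) and Cst9 (0.89 ± 0.053) rose, and Sycp1 (-0.87 ± 0.043), Smc1b (-0.56 ± 0.047), Cylc1 (-0.52 ± 0.041), Cylc2 (-0.42 ± 0.036) and Rpl26 (-1.02 ± 0.051) fell. For Rpl26 and Cylc2, 6 of the 9 treated libraries lay below the controls, and Rpl26 rose at 100 mg/kg (1.11 ± 0.059, adjusted p = 6.43e-13). Without the 100 mg/kg libraries, a fit added after the data were seen, Sycp1 stood on the log2 scale at -0.53, Smc1b at -0.27, Cylc1 at -0.28, Cylc2 at -0.063 and Rpl26 at -2.08, and Pm20d2 went from -1.32 ± 0.23 to -0.77. Cylc2 lost its call at adjusted p = 0.0643 without the 100 mg/kg libraries, within 8.12e-24 to 0.0643 over all its alternatives.

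In the mean of the doses 7 lists fell. Of 25 Sertoli cell markers, 1 rose and 10 fell (1 and 11 adjusted over the list alone). The Sertoli cell list had a median log2 fold change of -0.16 (camera adjusted p = 0.00833, adjusted p = 0.388 with an estimated correlation), with Clu at -0.31 ± 0.034 and Ctsl at -0.27 ± 0.031. Among 23 genes of cholesterol synthesis, 0 rose and 12 fell (0 and 12 adjusted over the list alone). The cholesterol synthesis list had a median log2 fold change of -0.18 (camera adjusted p = 0.0102, adjusted p = 0.196 with an estimated correlation), with Sqle at -0.22 ± 0.040 and Idi1 at -0.31 ± 0.059. For 13 complement genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone). The complement list had a median log2 fold change of -0.23 (camera adjusted p = 0.0273, adjusted p = 0.29 with an estimated correlation), with C4b at -0.38 ± 0.059 and C3 at -0.46 ± 0.11. In the mitochondrially encoded list of 12 genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone). The mitochondrially encoded list had a median log2 fold change of -0.16 (camera adjusted p = 0.0298, adjusted p = 0.649 with an estimated correlation), with mt-Nd5 at -0.45 ± 0.039, mt-Nd1 at -0.22 ± 0.051 and mt-Nd3 at -0.42 ± 0.14. Of 59 genes of the axoneme, 4 rose and 26 fell (6 and 30 adjusted over the list alone). The axoneme list had a median log2 fold change of -0.093 (camera adjusted p = 0.0127, adjusted p = 0.332 with an estimated correlation), with Cfap52 at -0.23 ± 0.037, Dnah17 at -0.32 ± 0.050 and Hydin at -0.28 ± 0.045. Of 20 blood-testis barrier genes, 2 rose and 8 fell (2 and 9 adjusted over the list alone). The barrier list had a median log2 fold change of -0.16 (camera adjusted p = 0.0273, adjusted p = 0.449 with an estimated correlation), with Gja1 at -0.35 ± 0.049, Itgb1 at -0.31 ± 0.052 and F11r at -0.45 ± 0.068. Of 24 fibroblast and matrix genes, 0 rose and 8 fell (0 and 8 adjusted over the list alone). The fibroblast list had a median log2 fold change of -0.085 (camera adjusted p = 0.0298, adjusted p = 0.31 with an estimated correlation), with Ogn at -0.87 ± 0.060, Fmod at -1.25 ± 0.19 and Dcn at -0.44 ± 0.044. Without the 100 mg/kg libraries the medians were -0.031 for the axoneme and -0.070 for the barrier, and Hydin stood on the log2 scale at -0.066, Dnah17 at -0.079, F11r at -0.27, Itgb1 at -0.17 and Idi1 at -0.13. The length correction gave -0.059 for the axoneme, with Hydin at -0.15 and Dnah17 at -0.20. The fibroblast median was -0.21 without control library 1 and -0.14 without 200 mg/kg library 1 or library 2. The mitochondrially encoded median was -0.10 without control library 1, and the cholesterol median -0.11 without control library 3. The mitochondrially encoded list lost its call at adjusted p = 0.059 to 0.117 without control library 1 or 100 mg/kg library 1 or 2, within 0.0018 to 0.649 over all its alternatives. The axoneme lost its call at adjusted p = 0.153 without the 100 mg/kg libraries, within 0.000856 to 0.332 over all its alternatives. The barrier lost its call at adjusted p = 0.0817 without the 100 mg/kg libraries, within 0.00261 to 0.449 over all its alternatives. The fibroblast list lost its call at adjusted p = 0.0523 without 100 mg/kg library 1, 0.0526 after the length correction, 0.0518 without the 100 mg/kg libraries, within 0.000488 to 0.31 over all its alternatives. Hydin lost its call at adjusted p = 0.196 without the 100 mg/kg libraries, within 3.77e-08 to 0.196 over all its alternatives. The mt-Nd3 call was lost at adjusted p = 0.0761 without control library 2 and 0.134 without control library 3, 0.0674 in DESeq2, within 0.00258 to 0.134 over all its alternatives.

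Of 25 NF-kB genes in the mean of the doses, 2 rose and 4 fell (2 and 4 adjusted over the list alone). The NF-kB list had a median log2 fold change of -0.037 (camera adjusted p = 0.655, adjusted p = 0.745 with an estimated correlation). Tnfrsf1b fell (-0.69 ± 0.17, adjusted p = 0.00348), Myd88 rose (0.32 ± 0.080, adjusted p = 0.00394) and Il1r1 fell (-0.31 ± 0.082, adjusted p = 0.00533). Il1b (0.24 ± 0.24), Nfkb1 (-0.12 ± 0.073), Rela (-0.039 ± 0.056), Tlr4 (-0.51 ± 0.31), Hmox1 (-0.24 ± 0.12), Nqo1 (0.013 ± 0.15), Sod2 (0.0018 ± 0.048), Gpx4 (0.089 ± 0.055) and Sirt1 (-0.052 ± 0.055) did not pass (adjusted p from 0.117 to 0.983). Cat (-0.33 ± 0.088, adjusted p = 0.00703), Star (-0.12 ± 0.040, adjusted p = 0.0222), Cyp11a1 (-0.45 ± 0.044, adjusted p = 5.27e-08), Cyp17a1 (-0.12 ± 0.034, adjusted p = 0.00807), Akap4 (-0.17 ± 0.029, adjusted p = 0.000154), Dnah1 (-0.18 ± 0.037, adjusted p = 0.000939) and Cldn11 (-0.18 ± 0.044, adjusted p = 0.00332) fell. Tnp1 (0.55 ± 0.13, adjusted p = 0.00675) and Ldhc (0.12 ± 0.029, adjusted p = 0.00291) rose. Hsd17b3 (-0.0051 ± 0.048), Prm1 (0.10 ± 0.069), Catsper1 (-0.019 ± 0.037), Gapdhs (0.029 ± 0.044), Cdkn1a (0.062 ± 0.10) and Adgre1 (0.084 ± 0.14) did not pass (adjusted p from 0.3 to 0.951). Without the 100 mg/kg libraries Star stood at 0.075, Gpx4 at -0.097 and Gapdhs at -0.15, each with the opposite sign. Gpx4 (adjusted p = 0.00545, within 0.00545 to 0.636 over all its alternatives) and Gapdhs (adjusted p = 7.53e-06, within 7.53e-06 to 0.967) passed there as falls. The same fit had Cat at -0.15, Tnp1 at 0.31, Akap4 at -0.090, Dnah1 at -0.083, Ldhc at 0.029 and Il1r1 at -0.19, and the length correction had Dnah1 at -0.058 and Ldhc at 0.073. Star, which fell in the mean, rose at 50 mg/kg (0.32 ± 0.048). Star lost its call at adjusted p = 0.0603 without control library 1 and 0.12 without control library 3, 0.0754 on library size alone, 0.0867 without the 100 mg/kg libraries, within 0.0097 to 0.12 over all its alternatives. Cyp17a1 lost its call at adjusted p = 0.0711 without control library 1, within 1.26e-06 to 0.0711 over all its alternatives. Cat lost its call at adjusted p = 0.168 without the 100 mg/kg libraries, within 7.23e-05 to 0.168 over all its alternatives. Tnp1 lost its call at adjusted p = 0.144 without the 100 mg/kg libraries, within 0.000316 to 0.144 over all its alternatives. Ldhc lost its call at adjusted p = 0.263 without the 100 mg/kg libraries, within 5.16e-08 to 0.263 over all its alternatives. Dnah1 lost its call at adjusted p = 0.233 after the length correction, within 7.21e-06 to 0.233 over all its alternatives. Tnfrsf1b lost its call at adjusted p = 0.0761 without control library 2, within 9.03e-05 to 0.0761 over all its alternatives. Il1r1 lost its call at adjusted p = 0.0593 without control library 1, 0.0697 without the 100 mg/kg libraries, within 0.00225 to 0.0697 over all its alternatives. Myd88 lost its call at adjusted p = 0.0569 without control library 3, within 0.000413 to 0.0569 over all its alternatives. Rela gained a call at adjusted p = 0.0264 without the 100 mg/kg libraries, within 0.0264 to 0.881 over all its alternatives. Tlr4 gained a call at adjusted p = 0.0409 in limma voom, within 0.0409 to 0.737 over all its alternatives. Hmox1 gained a call at adjusted p = 0.0342 without control library 2 and 0.0333 without 200 mg/kg library 3, 0.018 without the 100 mg/kg libraries, within 0.018 to 0.606 over all its alternatives.

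For the mean of the doses 4685 genes differed from saline, 2132 higher and 2553 lower, and 290 of them by at least 2-fold (233 higher, 57 lower). The 9 treated and 3 control libraries did not overlap in 1616 of the called genes and in 10.7% of all genes (chance 0.909%). In 40 of the 61 named genes that passed, 20 of the 40 chosen for it, all 9 treated libraries lay beyond the controls, and in the other 21, such as Rpl26, Cylc2 and Star (6 of 9), fewer did. Library size scaling gave 2572 higher and 2017 lower. Without the 100 mg/kg libraries 4644 genes were called, 2807 of them among the 4685.

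Genes called at all 3 doses in the same direction numbered 760, of which 505 were higher and 255 lower, and 89 were higher and 12 lower by at least 2-fold at every dose. Ibsp, Pcdh9 and Casq1 were among those higher and C1rb and Zfp951 among those lower. Independent lists of these sizes would share 38 and 28. The pair of 50 and 200 mg/kg shared 1488 calls in the same direction (915 higher, 573 lower, against 148 and 104 for independent lists) and had 37 in opposite directions. The 50 and 100 mg/kg comparisons shared 1288 (733 and 555, against 369 and 337) with 435 opposite, and the 100 and 200 mg/kg comparisons shared 1258 (754 and 504, against 412 and 349) with 546 opposite. The 3 comparisons use the same controls. In 20 simulations of unchanged groups with shared controls at most 1 call was shared, the mean correlation of fold changes was 0.499 and the mean covariance 0.0167. Observed correlations were 0.46 (50 and 100 mg/kg), 0.689 (50 and 200) and 0.419 (100 and 200), and covariances 0.0963, 0.114 and 0.0912. Part of the excess may come from the shared controls. The simulations gave the controls no shift, and 3 controls cannot be split into groups of at least 2.

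Doses were compared with each other to see which genes depended on dose. Rpl26 averaged 77.8 ± 1.7 CPM at 50, 265 ± 26 at 100 and 10.8 ± 1.2 at 200 mg/kg, and Rps2 7.78 ± 0.42, 158 ± 16 and 102 ± 4.5 CPM. Cwc22 averaged 12.3 ± 0.74, 64.3 ± 5.2 and 98.3 ± 5.2 CPM, and lies in a segment known to vary in copy number between mouse stocks. Pga5, Galntl6, Cylc2, the flagellar gene Fsip2, the retinoic acid enzyme gene Aldh1a1, Fnbp1l and the dynein light chain gene Dynlt1b made up the rest of the 10 smallest p-values, which ran from 5.64e-23 to 2.54e-13. In edgeR's joint test 8910 genes differed between the 3 doses. Pairwise, 8069 genes differed between 100 and 50 mg/kg, 8312 between 200 and 100 mg/kg and 792 between 200 and 50 mg/kg. Without the 100 mg/kg libraries 1689 genes differed.

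A linear trend with dose was called in 35 genes, 19 rising and 16 falling, and 1645 had an unadjusted p below 0.05. Zfp981 (2.09 ± 0.18), Zfp991 (1.60 ± 0.13), the adhesion receptor gene Adgrd1 (1.07 ± 0.12), Ceacam10 (1.22 ± 0.14) and the steroid 21-hydroxylase gene Cyp21a1 (0.48 ± 0.060) rose on the log2 scale per 100 mg/kg per day. Eml1 (-0.57 ± 0.086), the FGF co-receptor gene Klb (-0.39 ± 0.061), Muc15 (-0.47 ± 0.074), Gss (-0.57 ± 0.090) and the glutamine transporter gene Slc38a1 (-0.54 ± 0.089) fell, and adjusted p-values of the 10 genes ran from 0.000113 to 0.0252. The count was 6, 10 and 10 without control library 1, 2 and 3, of which 0, 1 and 2 fell. It was 7, 6 and 5 without 200 mg/kg library 1, 2 and 3, of which 1, 1 and 0 fell, and 89 without 100 mg/kg library 3, of which 42 fell. Eml1 lost its call at adjusted p = 0.0593 to 0.106 without control library 1 or 2 or 200 mg/kg library 1, 2 or 3, within 2.14e-05 to 0.106 over all its alternatives. Klb lost its call at adjusted p = 0.0561 to 0.106 without control library 1, 2 or 3 or 200 mg/kg library 1, 2 or 3, within 1.48e-06 to 0.106 over all its alternatives. Muc15 lost its call at adjusted p = 0.0688 to 0.106 without control library 1, 2 or 3 or 200 mg/kg library 2 or 3, within 0.000325 to 0.106 over all its alternatives. Gss lost its call at adjusted p = 0.0688 to 0.128 without control library 1 or 3 or 200 mg/kg library 1, 2 or 3, 0.0713 with dose rank, within 1.1e-06 to 0.128 over all its alternatives. Slc38a1 lost its call at adjusted p = 0.0897 to 0.128 without control library 1, 2 or 3 or 200 mg/kg library 1 or 3, within 1.74e-05 to 0.128 over all its alternatives. DESeq2 called 287, limma voom 1737, dose rank in place of dose 77, the length correction 72 and the fit without the 100 mg/kg libraries 1143.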

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

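The tests of repeat libraries, of the extract, of RNA fragmentation, of the length correction and of the near-silent genes were chosen after the result was seen. Those of linked inherited differences, of germ-cell makeup and of other splits of the libraries were not.

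Gene lists that passed in opposite directions at a pair of doses were set apart by the test between those doses. The nuclear oxidative phosphorylation list lay 0.43 higher at 100 than at 50 mg/kg as a median log2 difference (camera adjusted p = 2.26e-12, 0.497 with an estimated correlation). It stood at -0.49 at 200 against 100 mg/kg (camera adjusted p = 1.59e-13, 0.413 with an estimated correlation). After the length correction these medians were 0.23 and -0.25. Ribosomal protein genes lay 0.47 higher at 100 than at 50 mg/kg (camera adjusted p = 5.37e-17, 0.497 with an estimated correlation). They stood at -0.54 at 200 against 100 mg/kg (camera adjusted p = 1.6e-19, 0.378 with an estimated correlation). The correction gave 0.27 and -0.33. Antigen presentation genes lay at -1.41 at 200 against 100 mg/kg (camera adjusted p = 9.21e-05, 0.358 with an estimated correlation).

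Some genes differed far more between groups than between the replicates of a group. Of 64 genes with a mean of at least 5 CPM and a 4-fold range over the 12 libraries, 0 had a 4-fold range inside a group (median 42 and lowest 8 in 10000 random groupings), though 15 had a 2-fold range, the largest 3.66-fold. Repeat libraries of 1 animal or 1 pool per group would give this. An effect of the extract would of itself give only the gaps between groups. After the length correction control stood at least 2-fold apart from the 3 doses in 102 genes (90 lower, 12 higher). Single doses had 32 (50), 159 (100) and 24 (200 mg/kg). This leaves the extract and a separate control preparation open. Inherited differences between animals of this outbred stock, linked along chromosomes, may also contribute. The 2 neighbouring pairs found equal the bound of 2 set beforehand for no linkage (95th percentile of random sets, 5.34% with as many). Reading a value at the bound as open was decided after it was seen.

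The fold changes at 100 mg/kg followed transcript length, with a rank correlation of -0.415. Length as the whole cause of the calls is argued against by the correction, after which 73.9% of the genes called at 100 mg/kg were still called. A germ-cell shift towards late spermatids that moves their genes alike is argued against as the trend's cause. Inside 148 genes of late sperm lists the trend held (-0.735, bootstrap interval -0.808 to -0.644). Stage differences among them were not tested, so other shifts stay open. A difference in RNA fragmentation or library preparation may account for the trend, since libraries deviated along length from the others of their own group. At 100 mg/kg libraries 1, 2 and 3 stood at 0.308, 0.181 and -0.355, and at 50 mg/kg at -0.226, 0.165 and 0.111. These are not independent, as each enters the mean the others are set against. A regulated change in transcripts by length was not tested and stays open.

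Near-silent genes were lower in control libraries than in treated libraries. A uniform background of reads in the treated libraries stays open. The rise per gene was 11.2 times larger at 0.1 to 0.5 CPM (0.0443 CPM) than under 0.02 CPM (0.00396 CPM). The 0.02 limit leaves no room for the larger rise, so the ratio decides nothing. A separate preparation of the control libraries could give the pattern and cannot be told apart from the treatment, though all 12 libraries carried the same batch label. The 1188 genes under 0.02 CPM summed to at most 8.48 CPM in a control library and to 9.71 to 15.4 CPM in the treated ones. Olfactory receptor genes summed to 134 to 140 CPM in controls and 173 to 180 CPM in treated libraries. A biological effect of the extract on silent genes was not tested.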

How the results depend on the processing

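The length correction, the fit without the 100 mg/kg libraries and the 2-fold limit on calls were chosen after the results were seen. Of 581 values of called gene lists under the alternatives, 522 kept direction and side of the threshold and 59 lost the call; of 6937 values of named genes, 6797 kept both, 99 lost a call, 36 gained one and 5 turned. The cause was not tested for any change below unless given. Turned values were, after the length correction at 100 mg/kg, Dnah1 at 0.16 and Chd5 at 0.032, and, without the 100 mg/kg libraries for the mean of the doses, Gpx4 at -0.097, Star at 0.075 and Gapdhs at -0.15. Genes called at 50 mg/kg numbered 2701, but 4145 with limma voom, 404 at an unadjusted p with a 2-fold limit and 309 with that limit on the calls. The same limits gave 700 and 679 at 100 mg/kg, 418 and 350 at 200 mg/kg and 318 and 290 for the mean of the doses, since a fold limit takes genes away. A fit of the 2 groups alone called 4439 at 200 mg/kg. Without the 100 mg/kg libraries 1689 genes differed between doses. The dose trend had 287 genes with DESeq2, 1737 with limma voom, 77 with dose rank, 72 after the length correction and 1143 without the 100 mg/kg libraries. Lists called at 50 mg/kg numbered 9 without the count filter and 9 with fry; fry called 23 at 100 mg/kg, 17 at 200 mg/kg and 17 for the mean, and an estimated correlation 0 in each (smallest adjusted p 0.108, 0.423, 0.0906 and 0.196). Leaving out 1 library gave 1714 to 4013 genes at 50 mg/kg, 7348 to 8245 at 100 mg/kg, 1941 to 4181 at 200 mg/kg, 3202 to 5367 for the mean, 8186 to 8821 between doses and 5 to 89 for the trend. It gave 513 to 1082 genes shared by all 3 doses, and 3 to 8, 7 to 9, 10 to 13 and 5 to 8 lists. Without 100 mg/kg library 3, whose voom weight of 0.245 was the lowest of the 12, 7448 genes were called at 100 mg/kg. With replicate number as a block the trend had 6 genes and the other counts were 2473, 8095, 2718, 4477 and 8714 genes and 5, 8, 12 and 8 lists; Tnp1 at 50 mg/kg gained a call, and with 6 trend genes rising and 0 falling, Eml1, Klb, Muc15, Gss and Slc38a1, the named falls of the trend, lost theirs. In the 4 comparisons with saline the block changed no other call of a named gene or called list. The 5 named rises of the trend passed in all 22 alternatives and the 10 genes named between doses in all 21. The numbers do not pair the libraries: 18 same-numbered pairs correlated at -0.307 to 0.131, 3 of them over 0.1, and 0 libraries correlated best with their own number throughout. Under the scaling alternatives the median log2 fold change of all genes lay between -0.00746 and 0.0324, against -0.00822 to 0.00857 in the main fit. Depth limits low genes: Tnf, Il6, Nlrp3 and Ccl2, with 6, 0, 25 and 24 counts over the 12 libraries, were under the count filter.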

Other observations

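The tests of other splits of the libraries were set beforehand, and the gene groups described first were picked after their values were seen. The piRNA pathway silences transposons in germ cells, and its list did not pass at 100 mg/kg. Of 23 piRNA genes (median length 2586 bases), 3 rose and 13 fell (3 and 13 adjusted over the list alone). The piRNA list had a median log2 fold change of -0.25 (camera adjusted p = 0.0554, adjusted p = 0.584 with an estimated correlation). This list had adjusted p = 0.0277 after the length correction, in a range of 0.000868 to 0.584 over fry, that correction and the estimated correlation. Tdrd6 stood at -0.74 ± 0.057 on the log2 scale in edgeR (adjusted p = 9.84e-10), Mybl1, a transcription factor of spermatocytes, at -0.73 ± 0.064 and Rnf17 at -0.58 ± 0.056.

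Of 6 lymphocyte markers measured (median length 1623 bases), 2 rose and 0 fell at 100 mg/kg (2 and 0 adjusted over the list alone). At 200 mg/kg 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0503, adjusted p = 0.24 with an estimated correlation). That list passed after the length correction (adjusted p = 0.0435, in a range of 0.00245 to 0.24 over fry, that correction and the estimated correlation). The T cell receptor gene Cd3d rose at 100 mg/kg (0.91 ± 0.10, edgeR adjusted p = 9.91e-08) and at 200 mg/kg (0.41 ± 0.11, adjusted p = 0.00819). Between 200 and 50 mg/kg 6 lists passed camera's test, all downward at 200 mg/kg. Of 15 antigen presentation genes, 1 was higher and 8 lower (1 and 9 adjusted over the list alone). The antigen presentation list had a median log2 fold change of -0.66 (camera adjusted p = 5.19e-07, adjusted p = 0.182 with an estimated correlation). Cd74, the invariant chain of class II molecules, stood at -1.80 ± 0.20, H2-Ab1 at -1.46 ± 0.17 and B2m at -0.66 ± 0.087. Of 18 macrophage markers, 0 were higher and 4 lower (0 and 4 adjusted over the list alone). The macrophage list had a median log2 fold change of -0.31 (camera adjusted p = 0.000287, adjusted p = 0.0611 with an estimated correlation), with Fcgr3 at -0.49 ± 0.091 and Lyz2 at -0.41 ± 0.082. Of 13 complement genes, 0 were higher and 3 lower (0 and 4 adjusted over the list alone). The complement list had a median log2 fold change of -0.24 (camera adjusted p = 0.0231, adjusted p = 0.195 with an estimated correlation). Of 12 mitochondrially encoded genes, 0 were higher and 1 lower (0 and 2 adjusted over the list alone). The mitochondrially encoded list had a median log2 fold change of -0.15 (camera adjusted p = 0.012, adjusted p = 0.711 with an estimated correlation). Of 25 Sertoli cell markers, 0 were higher and 4 lower (0 and 4 adjusted over the list alone). The Sertoli cell list had a median log2 fold change of -0.10 (camera adjusted p = 0.0226, adjusted p = 0.66 with an estimated correlation). Of 76 ribosomal protein genes, 1 was higher and 5 lower (1 and 7 adjusted over the list alone). The ribosomal list had a median log2 fold change of -0.073 (camera adjusted p = 0.00124, adjusted p = 0.893 with an estimated correlation). Fits after the length correction and without each library were added for these lists after the data were seen. The complement call was lost without 50 mg/kg library 3 (adjusted p = 0.0514) and 200 mg/kg library 1 (0.0755), within 0.000527 to 0.195 over all its alternatives. The mitochondrially encoded call was lost without 200 mg/kg library 2 (adjusted p = 0.0879, within 0.00344 to 0.711). The Sertoli cell call was lost without 50 mg/kg library 1 (adjusted p = 0.11, median -0.062) and 200 mg/kg library 2 (0.142), within 0.00488 to 0.66. The ribosomal median was -0.045 after the length correction. Fry did not call the mitochondrially encoded (adjusted p = 0.188), Sertoli cell (0.108) and ribosomal lists (0.632, within 5.38e-05 to 0.893). Of 13 xenobiotic response genes, compared between 200 and 100 mg/kg, 8 were higher and 0 lower (8 and 0 adjusted over the list alone). The xenobiotic list had a median log2 fold change of 0.52 (camera adjusted p = 0.0417, adjusted p = 0.358 with an estimated correlation). This call was lost after the length correction (adjusted p = 0.0535) and without 100 mg/kg library 2 (0.0521) or library 3 (0.0514), within 3.51e-05 to 0.358 over all its alternatives. The efflux transporter gene Abcg2 was higher by 0.52 ± 0.060 and Tiparp by 0.49 ± 0.066.

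Other splits show whether chance can be excluded for independent libraries. If the 3 libraries of a group were repeats of 1 animal or 1 pool, which stays open, any split that breaks a group loses calls, and chance differences between animals are not excluded by any count here. For single doses the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 2701, 8212 and 2914 genes at 50, 100 and 200 mg/kg, each in 1 of 10 splits, with a highest other of 0. They gave 5 lists (2 of 10 splits as many, highest other 7), 8 lists (1 of 10, highest other 4) and 11 lists (1 of 10, highest other 6). For the mean of the doses 1 of 100 splits gave 4685 genes (highest other 160). Breaking up the 100 mg/kg group costs calls, so with independent libraries this excludes only that all 4 groups are alike. Chance is not excluded for the 7 lists (17 of 100, highest other 11). On the same condition the 8910 genes differing between doses (1 of 70) exclude only that all 3 are alike. The highest other, 7494, kept the 100 mg/kg group. For the 760 genes shared by all 3 doses the splits decide nothing (1 of 100, highest other 0). Other splits of single doses gave 0 genes to share, a reading made after the count was seen. For the 35 genes of the trend 3 of 100 splits gave as many, and a split with the 100 mg/kg libraries at the highest dose gave 5589, which points to a structure of the samples.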
